A study of Mus musculus with 10 samples.

How the data were processed

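The 10 libraries analysed came from sorted fluorescent cells of pups on postnatal day 3, 5 Ctrl and 5 Cdk7_KO. The deposited table holds whole-number counts per gene for each library, not normalized. Per the submitters' processing notes, STAR and Salmon were used with the GRCm38 build. Their versions, the step each was used for and the strand setting of the counting are not given in the sources used here. Per the labels, RNA was polyA-selected and libraries were made with a directional kit. Because the strand setting is not stated, reads of overlapping antisense genes may be counted together. Genes with near-identical copies, such as globin, histone and ribosomal protein genes, may share reads.

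The table lists 55573 Ensembl gene IDs, of which 28204 had at least 1 count. Coordinates, lengths and biotypes came from GENCODE M21, where 55480 IDs matched and 93 did not. Every count column was matched to a sample by its name, and 0 columns were left over. For 117 symbols shared by more than 1 ID, the ID with the most counts was used for list members and named genes. The smallest chi-square per gene of any pair of libraries was 11.2, so that no library was a copy of another. Total counts lay between 23497621 and 31233466, and Cdk7 had between 93 and 575 counts per library. Counting error weighs most on weakly expressed genes.

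Counts were tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr by group (minimum count 10), TMM factors, estimateDisp, glmQLFit and glmQLFTest, with genotype alone in the model and Benjamini-Hochberg adjustment over 15578 genes at a threshold of 0.05. Fold changes are Cdk7_KO over Ctrl on the log2 scale, with standard errors taken from the F statistic. CPM values use library totals without TMM factors. Cdk7, as log2(CPM + 1), and whole-library measures were also compared by two-sided exact permutation tests over the 252 assignments of 5 and 5 libraries. DESeq2 1.42.0 (Wald test, default filtering) and limma 3.58.1 (voom) were alternatives. DESeq2 left 12037 adjusted p-values as missing, and these were not counted.

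The 45 lists hold 1023 entries for pathways, neuron classes and other cell types that a cortical sort could hold, of which 977 were measured. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. A library's list score is its mean log2 CPM (TMM-scaled, prior count 2). The other-cell index is the mean of the scaled scores of 4 lists (astrocytes, microglia and macrophages, endothelial cells and pericytes, oligodendrocyte lineage).

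The rule for named genes took Cdk7, then the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among edgeR calls with a mean of at least 1 CPM and no overlap between groups, leaving out predicted and clone models, Y-linked genes, Xist and Tsix. It then took up to 4 members with the smallest adjusted p of each list that camera called and up to 2 of any other list. As edgeR called 0 genes, its second part named none and was applied to DESeq2's calls.

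Alternatives fixed in advance were DESeq2, voom, RLE size factors, library totals, no filter, a mean of at least 1 CPM, robust estimation, glmTreat at a log2 fold change of 0.5, leaving out each library, the replicate number as a block, 1 surrogate variable (sva 3.50.0), the level of Xist, and leaving out Y-linked genes with Xist and Tsix. For the length trend they were exon length and a mean of at least 5 CPM, and for summed CPM TMM scaling. Sex as a factor, the index as covariate, both together, 2 surrogate variables, male or female libraries alone, the further settings of DESeq2 and leaving out each library for the length trend were added after the data were seen.

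The tests were tried on simulated counts for 15578 genes with the means, dispersions and sizes of these libraries and 200 genes changed. Of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, edgeR recovered 44%, 74%, 86% and 88%, and DESeq2 52%, 86%, 86% and 92%. Each gene was drawn independently, without variation shared between genes, so these rates may not carry over to the real libraries.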

Results

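RNA was measured by polyA-selected, stranded sequencing in projection neurons of the mouse cortex that had been sorted for a yellow fluorescent reporter on postnatal day 3. The reporter and the deletion both depended on NexCre, a Cre recombinase expressed from the Neurod6 locus in young glutamatergic neurons of the dorsal forebrain. The 5 Cdk7_KO libraries came from pups with floxed Cdk7 alleles, and the 5 Ctrl libraries from pups with wild-type Cdk7, the driver and the reporter. Total counts per library lay between 23497621 and 31233466, and between 19467 and 21583 genes had at least 1 count. Xist and the Y-linked gene Ddx3y marked 2 Ctrl and 3 Cdk7_KO libraries as male and 3 Ctrl and 2 Cdk7_KO libraries as female. The male libraries carry the replicate numbers 1 to 3 and the female ones 4 to 6, so sex and any difference between these sets of preparations cannot be told apart. The comparison of the genotypes asks what loss of Cdk7, the kinase of the CDK-activating complex and of the general transcription factor TFIIH, does to RNA levels in these neurons.

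Cdk7 RNA was low in each of the 5 Cdk7_KO libraries. Its level, in counts scaled to each library total (CPM), was 15.7 ± 4.0 CPM in Ctrl and 5.16 ± 1.3 CPM in Cdk7_KO (SD, n = 5), so that 33.0% of the Ctrl mean was left. The lowest Ctrl library (10.1 CPM, replicate 3) lay above the highest Cdk7_KO library (7.07 CPM, replicate 1). The two-sided exact permutation p was 0.0079, the smallest that 252 assignments of the libraries can give. The log2 fold change was -1.54 (SE 0.22, 95% interval -2.03 to -1.06). Cdk7 had the smallest p of all genes in edgeR's quasi-likelihood test and did not pass the correction over 15578 genes (edgeR adjusted p = 0.161). DESeq2 gave an adjusted p of 2.25e-08, and over 27 alternatives the adjusted p of edgeR, limma or DESeq2 ranged from 2.25e-08 to 1.00. The gene (ENSMUSG00000069089) spans chromosome 13 from 100702631 to 100730939 in GRCm38. The counts are for whole genes, so they do not show which exons the remaining reads came from.

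**Figure D1:**
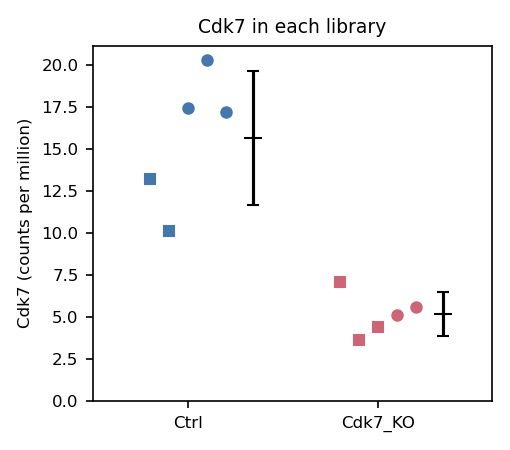
Cdk7 in CPM (vertical axis) in the 5 Ctrl and the 5 Cdk7_KO libraries. Each symbol is 1 library (squares, male, circles, female, as read from the RNA), the bar beside each group is the mean with its SD, and the Cdk7_KO libraries all lie below the lowest Ctrl library at 10.1.

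Marker genes of cells that NexCre does not mark were lower in Cdk7_KO. Genes of radial glia, astrocytes, vessels, blood, oligodendrocytes and microglia fell as lists, as did proliferation genes, while genes of immature projection neurons rose. Camera did not call the lists for upper and deep cortical layers over all libraries. Of 45 gene lists fixed before the data were examined, limma's camera called 17 lower and 7 higher (preset correlation 0.01). With an estimated correlation it called 0, the smallest adjusted p being 0.250. In fry 0 lists moved one way (smallest adjusted p 0.0722) and 9 changed in either direction, those of TFIIH, RNA polymerase II subunits, proliferation, cell cycle CDKs, radial glia, interferon-stimulated genes, ATF4 targets, retinoid signalling and thyroid hormone responsive genes. The TFIIH list holds Cdk7, the deleted gene, and was not tested without it, so its result says little about the other members. Over all genes edgeR called 0 members of any list, and counts of members given below are adjusted over the list alone in edgeR.

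Radial glia and apical progenitor genes fell in camera (adjusted p = 1.80e-15, 0.250 with an estimated correlation). Their median log2 fold change was -0.89, and all 14 measured members were negative and passed when adjusted over the list alone. Notch1, the receptor that keeps progenitors undifferentiated, was at 87.4 ± 10.8 CPM in Ctrl and 42.0 ± 17.1 CPM in Cdk7_KO (SD, n = 5), a log2 fold change of -1.01 (SE 0.22). The intermediate filament gene Vim was at -1.14 (SE 0.28). Astrocyte genes fell likewise (adjusted p = 1.18e-12, 0.250 with an estimated correlation), with a median of -1.08, 14 of 14 negative and 12 passing when adjusted over the list alone. Examples were the glutamate transporter gene Slc1a2 (-0.84), the water channel gene Aqp4 (-1.20) and Gfap (-1.30). In the male libraries the medians of the radial glia and astrocyte lists were -0.68 and -0.87, and in the female libraries -1.42 and -2.01. With an index of 4 lists of other cell types (astrocytes, microglia, vessels and oligodendrocytes) as covariate, the radial glia list had a median of -0.20 and was not called (camera adjusted p = 0.0708). The index did not overlap between genotypes (lowest 0.292 in Ctrl, highest 0.0787 in Cdk7_KO), so it also takes up genotype. Cdk7 itself was not called by edgeR in that fit (log2 fold change -1.62, adjusted p = 0.9998). A call lost with the index, here and below, thus does not show other cells as the source.

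Genes of endothelial cells and pericytes had a median of -1.62 and fell in camera (adjusted p = 7.35e-10, 0.287 with an estimated correlation), with 16 of 16 members passing when adjusted over the list alone. Among them were the VEGF receptor gene Flt1, at 42.1 ± 39.1 CPM in Ctrl and 11.9 ± 6.14 CPM in Cdk7_KO (SD, n = 5), a log2 fold change of -1.79, and the pericyte gene Rgs5 (-1.60). The median was -2.21 in the male and -1.05 in the female libraries, and -0.85 without Ctrl replicate 1 (Flt1 -1.06, Rgs5 -1.02), whose vascular markers summed to 1544 CPM against at most 648.5 CPM in the other Ctrl libraries. The 5 measured genes of erythroid cells fell (median -1.23, adjusted p = 6.65e-07, 0.250 with an estimated correlation), and all 5 passed when adjusted over the list alone. The globin genes Hba-a1 and Hbb-bs, which have near-identical copies, were at -1.39 and -1.18. With the other-cell index as covariate the erythroid list was called (camera adjusted p = 1.07e-05, 0.805 with an estimated correlation). Oligodendrocyte lineage genes fell (median -0.88, adjusted p = 6.76e-07, 0.250 with an estimated correlation), with 1 of 12 passing when adjusted over the list alone, Cnp at -0.97 and Cspg4 at -0.88. Their median was -0.39 in the male libraries, where the list was not called (camera adjusted p = 0.0561), and -1.30 in the female libraries. Microglial genes fell (median -0.84, adjusted p = 6.76e-07, 0.376 with an estimated correlation), with 0 of 17 passing when adjusted over the list alone, 8 at an unadjusted p under 0.05, Csf1r at -0.87 and C1qa at -0.89, and a median of -0.48 without Ctrl replicate 3 (Csf1r -0.45, C1qa -0.53).

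Interneuron genes fell in camera over all libraries (median -0.84, adjusted p = 2.11e-05, 0.495 with an estimated correlation), with 20 of 20 negative. Maf was at 16.9 ± 6.01 CPM in Ctrl and 8.16 ± 5.13 CPM in Cdk7_KO (SD, n = 5), and Gad2, which encodes a GABA-synthesising enzyme, had a log2 fold change of -0.94. The interneuron median was 0.46 in the male and -2.06 in the female libraries, -1.33 without Cdk7_KO replicate 1 (Gad2 -1.41), and 0.25 with the other-cell index as covariate (camera adjusted p = 0.0769). Cajal-Retzius genes fell (median -0.52, adjusted p = 0.00944, 0.595 with an estimated correlation), with Reln at -0.63 and Ndnf at -0.66. They were not called without Cdk7_KO replicate 1 or 4 or Ctrl replicate 4 (camera adjusted p = 0.0723, 0.0608 and 0.0943), nor in the male libraries (median -0.23, adjusted p = 0.608, against -1.01 in the female ones). Fibroblast and meningeal genes fell (median -1.67, adjusted p = 0.00365, 0.250 with an estimated correlation), with the collagen genes Col1a2 at -1.86 and Col3a1 at -1.78. Choroid plexus and ependymal genes fell (median -0.76, adjusted p = 0.00964, 0.250 with an estimated correlation), with Foxj1, a regulator of motile cilia, at -1.25 and Enpp2 at -0.63, and a median of -1.33 without Cdk7_KO replicate 2. When adjusted over the list alone, 2 choroid plexus genes and 0 genes of the other lists in this paragraph passed. With the other-cell index the Cajal-Retzius (median -0.10, camera adjusted p = 0.999), fibroblast (-0.41, 0.748) and choroid plexus lists (-0.49, 0.103) were not called. Intermediate progenitor genes (median 0.12, camera adjusted p = 0.845) and hippocampal neuron genes (median -0.03, 0.870) were not called.

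**Figure D2:**
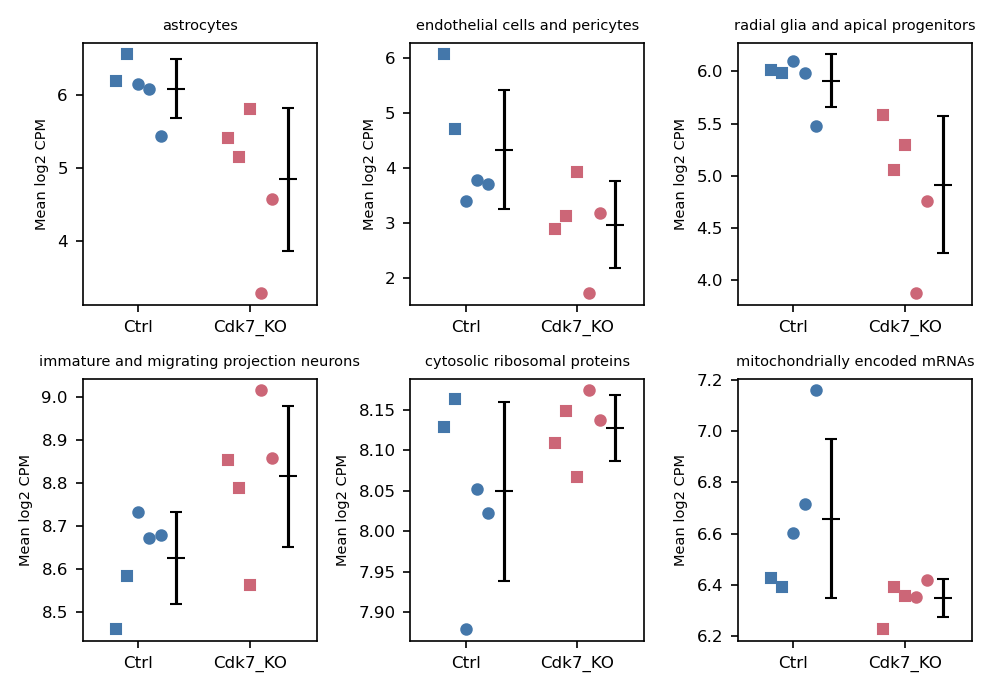
Library scores (mean log2 CPM of the measured members, vertical axes, each on its own scale) of 6 lists in the 5 Ctrl and 5 Cdk7_KO libraries. Squares are male and circles female libraries, bars are means with their SD, and the astrocyte score was 6.09 on average in Ctrl and 4.85 in Cdk7_KO.

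Proliferation genes fell (median -0.66, camera adjusted p = 8.23e-14, 0.250 with an estimated correlation), with 22 of 23 negative and 18 passing when adjusted over the list alone. Cell cycle CDKs and cyclins fell (median -0.34, adjusted p = 9.31e-04, 0.287 with an estimated correlation), with 14 of 20 negative and 5 passing. The topoisomerase gene Top2a was at 44.1 ± 8.26 CPM in Ctrl and 19.8 ± 8.72 CPM in Cdk7_KO (SD, n = 5), a log2 fold change of -1.11. Ccnb1 was at -0.97, Ccnd1 at -1.05 and Cdk2 at -1.01. With the other-cell index as covariate the medians were -0.15 (camera adjusted p = 0.0507) and -0.02 (0.810), and neither list was called.

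Genes of immature and migrating projection neurons rose (median 0.21, camera adjusted p = 9.78e-07, 0.287 with an estimated correlation), with 21 of 23 positive. Marcksl1 was at 1854 ± 117.0 CPM in Ctrl and 2132 ± 106.8 CPM in Cdk7_KO (SD, n = 5), a log2 fold change of 0.25. The transcription factor genes Neurod6, the locus of the driver, and Sox4 were at 0.34 and 0.27. Axon guidance genes were called higher (median 0.13, adjusted p = 0.0103, 0.287 with an estimated correlation), with 4 members higher and 2 lower when adjusted over the list alone. Besides Nrp2, the adhesion molecule gene Cntn2 (0.31) and the netrin receptor gene Unc5a (0.20) were examples of higher members. At an unadjusted p under 0.05 edgeR gave 6 axon guidance genes higher and 6 lower, and DESeq2 called 2 higher and 3 lower. Presynaptic genes rose (median 0.10, adjusted p = 0.00468, 0.482 with an estimated correlation), with Rab3a at 0.20 and the active-zone gene Bsn at 0.19. When adjusted over the list alone, 0 immature neuron and 0 presynaptic genes passed in edgeR, with 9 and 4 higher at an unadjusted p under 0.05. Of the 3 lists, camera called the presynaptic one with the other-cell index as covariate (median 0.12, adjusted p = 0.00152, 0.805 with an estimated correlation), and not the immature neuron (median -0.00, 0.780) or axon guidance genes (-0.06, 0.770). Presynaptic genes were not called without Cdk7_KO replicate 3 (camera adjusted p = 0.0756) and axon guidance genes not without Ctrl replicate 1 (0.0684), and the immature neuron median was 0.12 without Cdk7_KO replicate 4.

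The 11 measured mRNAs encoded in the mitochondrial genome were all lower in Cdk7_KO and fell as a list (median -0.28, camera adjusted p = 1.34e-04, 0.287 with an estimated correlation), with 6 passing when adjusted over the list alone. The complex I gene mt-Nd5 was at 989.8 ± 156.3 CPM in Ctrl and 775.2 ± 37.0 CPM in Cdk7_KO (SD, n = 5), a log2 fold change of -0.30, and mt-Co1 was at -0.23. Nuclear genes of oxidative phosphorylation were called higher (median 0.08, adjusted p = 4.84e-05, 0.595 with an estimated correlation), with 65 of 76 positive, Atp5g1 at 0.18 and Cox5b at 0.13. Cytosolic ribosomal protein genes were called higher (median 0.09, adjusted p = 6.65e-07, 0.595 with an estimated correlation), with 74 of 77 positive, Rpl15 at 0.15 and Rpl13 at 0.16. They took 2.69 ± 0.20% of counts in Ctrl and 2.75 ± 0.03% in Cdk7_KO (SD, n = 5, exact permutation p = 0.579, adjusted 0.624). Library totals in place of TMM factors shifted log2 fold changes over all genes by a median of -0.053, which is not small beside both medians. In edgeR 0 members of either nuclear list passed when adjusted over the list alone, and 8 of each were higher at an unadjusted p under 0.05. In the male libraries the medians were -0.06 for the mitochondrial, -0.02 for the nuclear and -0.03 for the ribosomal list, and in the female libraries -0.40, 0.14 and 0.18. The mitochondrial median was -0.18 without Ctrl replicate 6, and the nuclear and ribosomal medians were 0.04 and 0.04 without Ctrl replicate 4 and 0.05 and 0.06 without Cdk7_KO replicate 4.

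**Figure D3:**
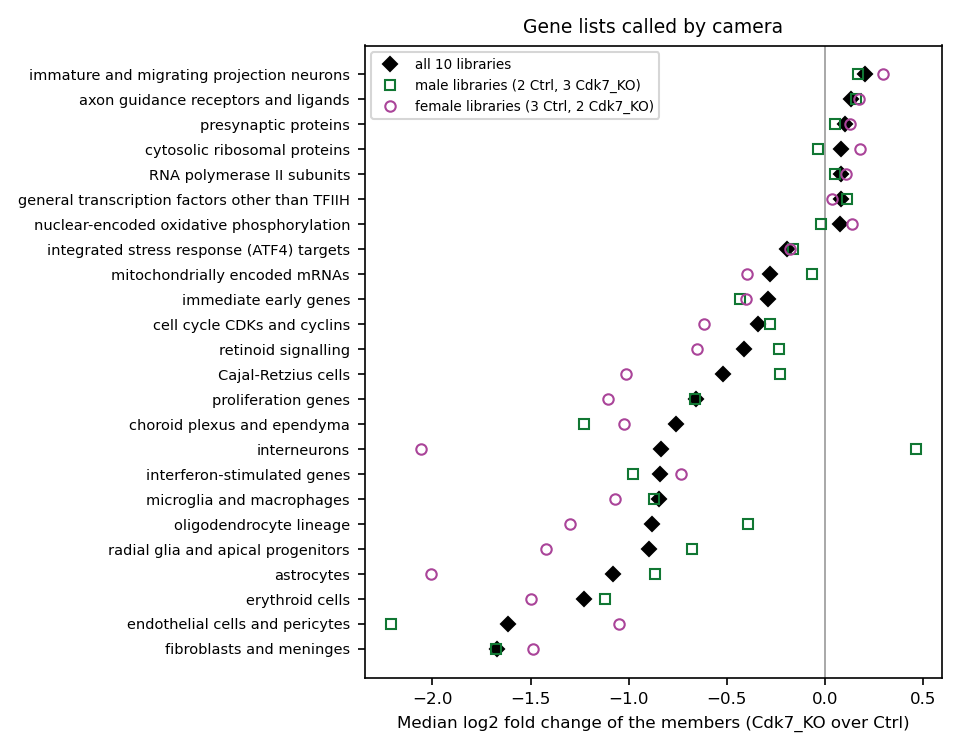
Median log2 fold change of the measured members (horizontal axis, Cdk7_KO over Ctrl) of the 24 lists that camera called, from all 10 libraries (diamonds), the male libraries alone (squares) and the female libraries alone (circles). Interneuron genes lie at 0.46 in the male and at -2.06 in the female libraries, and the ribosomal protein list at -0.03 and 0.18.

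RNA polymerase II subunit genes were called higher by a small amount (median 0.08, camera adjusted p = 0.00964, 0.250 with an estimated correlation), with 12 of 13 positive. Polr2a, the largest subunit, whose C-terminal repeats CDK7 phosphorylates, was at 191.0 ± 25.6 CPM in Ctrl and 234.5 ± 27.6 CPM in Cdk7_KO (SD, n = 5), a log2 fold change of 0.35, and Polr2m was at 0.15. General transcription factors other than TFIIH were called higher (median 0.08, adjusted p = 0.0337, 0.250 with an estimated correlation), with Taf3 at 0.30 and Gtf2a2 at 0.17. With library totals in place of TMM factors the median shift over all genes was -0.053, so the size of both rises depends on the scaling. When adjusted over the list alone, 0 members of either list passed in edgeR, with 2 and 1 at an unadjusted p under 0.05. With the other-cell index neither was called (adjusted p = 0.0861 and 0.540), and without Cdk7_KO replicate 1 or 4 or Ctrl replicate 3 the second was not (camera adjusted p = 0.0825, 0.051 and 0.0903). The TFIIH list, which holds Cdk7, was not called by camera (median -0.00, adjusted p = 0.435) and had the smallest adjusted p of fry for change in either direction (0.00216). Of its members 5 were positive, among them Gtf2h5 at 0.16, 5 were negative, and 1, Cdk7 itself, was lower when adjusted over the list alone. Other transcriptional kinases and elongation factors were not called (median 0.05, adjusted p = 0.192), with Cdk9 at 0.14 and Aff1 at -0.81.

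Of the stress and signalling lists, interferon-stimulated genes fell (median -0.84, camera adjusted p = 2.37e-05, 0.250 with an estimated correlation), with B2m at -1.22 and H2-K1 at -0.84, both of antigen presentation. The most abundant member of that list, H2-D1, was at -0.14 (42.5 CPM in Ctrl, 37.4 CPM in Cdk7_KO). ATF4 targets of the integrated stress response fell (median -0.19, adjusted p = 0.0120, 0.250 with an estimated correlation), with 3 of 29 passing when adjusted over the list alone. Psat1 (-0.45) and Mthfd2 (-0.53), enzymes of serine and folate metabolism, were examples. Retinoid signalling genes fell (median -0.41, adjusted p = 0.0323, 0.287 with an estimated correlation), with Stra6 at -1.59 and Rxrb at 0.19. Immediate early genes fell (median -0.29, adjusted p = 0.0354, 0.717 with an estimated correlation), with Egr1 at -0.63 and Egr2 at -0.93. Of 16 interferon-stimulated, 15 retinoid and 22 immediate early genes 0 passed when adjusted over the list alone in edgeR, with 6, 3 and 5 lower and 0, 1 and 0 higher at an unadjusted p under 0.05. With the other-cell index as covariate none of these 4 lists was called, with medians of -0.22, -0.05, 0.01 and 0.25. The retinoid list was not called without Cdk7_KO replicate 4 or 5 or Ctrl replicate 3 (camera adjusted p = 0.109, 0.0587 and 0.0524). Immediate early genes were not called without Cdk7_KO replicate 1, 4 or 5 or Ctrl replicate 1 or 3 (adjusted p = 0.0928, 0.188, 0.439, 0.561 and 0.297), and their median was 0.03 without Ctrl replicate 1. The ATF4 median was -0.12 without Ctrl replicate 4. The p53 target list (median -0.13, adjusted p = 0.0759, Tnfrsf19 -0.59) and the apoptosis list (-0.00, 0.928, Casp8 -1.45) were not called by camera, although p53 targets were called lower without Cdk7_KO replicate 3 or Ctrl replicate 6 (adjusted p = 0.0356 and 0.0399). With sex as a factor camera also called p53 targets lower (adjusted p = 0.0222, 0.219 with an estimated correlation). ER stress (-0.06, 0.0759, and 0.00998 and 0.00775 without Cdk7_KO replicate 5 or Ctrl replicate 4), heat shock (0.04, 0.828) and nucleotide excision repair genes (0.00, 0.866) were not called by camera either. In the male libraries ER stress genes were called lower (camera adjusted p = 0.0132, 0.542 with an estimated correlation).

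Over all libraries camera called none of the lists of cortical layers and subplate. Deep-layer genes had a median of 0.05 (camera adjusted p = 0.920), with Tbr1 at 0.37 (0.46 and an edgeR adjusted p of 0.0286 with sex as a factor) and Ccn2 at -1.15. They were called higher in the male libraries (median 0.18, camera adjusted p = 0.0286, 0.542 with an estimated correlation), and their median was -0.22 in the female ones. Upper-layer genes had a median of 0.07 (0.934), with Igfbp4 at -0.28 and Kcnh5 at -0.67. Subplate genes (-0.09, 0.0746), voltage-gated channels (0.02, 0.200, Kcnq3 0.40, Kcnj3 0.31), postsynaptic genes (0.04, 0.288) and injury-associated genes (-0.03, 0.289, Il6st -0.56) were not called by camera. Adjusted over the list alone, 2 subplate genes and 2 injury-associated genes were lower in edgeR, and the subplate list was called lower without Cdk7_KO replicate 2 or 3 or Ctrl replicate 6 (camera adjusted p = 0.0488, 0.0278 and 0.0415). With sex as a factor camera called the subplate list (median -0.21, adjusted p = 0.0291) and the injury-associated list (-0.13, 0.0163) lower. The injury-associated list was also called lower in the male libraries (-0.16, 0.00508). None of these 3 calls held with an estimated correlation (camera adjusted p = 0.279, 0.219 and 0.469). The channel list was called higher without Cdk7_KO replicate 1 (camera adjusted p = 0.0215) and in the male libraries (0.0196, 0.644 with an estimated correlation). Thyroid hormone responsive genes (-0.10, 0.0877, Dio2 -1.03), cholesterol synthesis (-0.05, 0.200), glycolysis (0.01, 0.934), mitochondrial biogenesis (-0.03, 0.845), lysosome and autophagy (0.02, 0.920) and histone genes (0.14, 0.394) were not called by camera. Thyroid hormone responsive genes changed in either direction in fry (adjusted p = 0.0351), with 3 lower when adjusted over the list alone, and were called lower by camera without Cdk7_KO replicate 3 or Ctrl replicate 6 (adjusted p = 0.0415 and 0.0399). With sex as a factor camera also called them lower (adjusted p = 0.0282, 0.454 with an estimated correlation). Cholesterol synthesis was called lower without Ctrl replicate 4 (camera adjusted p = 0.0171). In the male libraries camera called cholesterol synthesis and glycolysis lower (adjusted p = 0.00508 and 0.0211, 0.575 and 0.543 with an estimated correlation). In the upper-layer (mean -0.10), deep-layer (-0.02), intermediate progenitor (-0.08), glycolysis (-0.13), lysosome (-0.11), heat shock (-0.22), postsynaptic (-0.01), transcriptional kinase (-0.01) and nucleotide excision repair (-0.01) lists the mean was negative and the median positive.

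Among single genes, Nrp2, a semaphorin receptor of axon guidance, was at 83.6 ± 9.63 CPM in Ctrl and 139.0 ± 33.6 CPM in Cdk7_KO (SD, n = 5), a log2 fold change of 0.79 (SE 0.15, DESeq2 adjusted p = 7.94e-04, edgeR adjusted p = 0.161). Since edgeR called 0 genes, the genes in this paragraph were taken by the same rule from DESeq2's calls, after the values were seen, and 25 genes on the higher and 220 on the lower side fulfilled it. The other higher ones were Gng10 (log2 fold change 0.79), Mir6236 (0.59), Dtwd1 (0.54), Nudt16 (0.50), Cox11 (0.38), an assembly factor of cytochrome c oxidase, Osbp2 (0.37), Pcdhga8 (0.37), Shf (0.37) and Negr1 (0.35), a neuronal adhesion molecule. Whether Mir6236 rose through a source of reads shared with the noncoding transcript Gm42418, also higher, was not tested. The 10 with the most negative values were all under 6 CPM in Ctrl. They were Nos2 (-2.35), the inducible nitric oxide synthase, Scarf1 (-2.21), a scavenger receptor of endothelial cells, Serpina3n (-2.18), Higd1b (-2.09), Serpinb6b (-2.05), Msrb3 (-1.86), Ifitm3 (-1.82), an interferon-induced membrane protein, and the cilia genes Dnaic2 (-2.09), Dnah11 (-1.88) and Rsph4a (-1.84). Nos2 was at 2.64 ± 1.93 CPM in Ctrl and 0.498 ± 0.28 CPM in Cdk7_KO (SD, n = 5, DESeq2 adjusted p = 0.00223, edgeR adjusted p = 0.161). Ctrl replicate 1 stood apart, with high values, for Nos2, Scarf1, Dnaic2, Serpinb6b and Msrb3, and Ctrl replicate 5 for Serpina3n (10.1 CPM against at most 2.63 CPM). Without Ctrl replicate 1 the log2 fold changes were -1.79 for Nos2, -1.43 for Scarf1, -1.82 for Dnaic2, -1.19 for Serpinb6b and -1.10 for Msrb3, and without Ctrl replicate 5 it was -1.33 for Serpina3n.

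Over all genes, edgeR called 0 higher and 0 lower in Cdk7_KO (smallest adjusted p 0.161), limma voom 0 and 0, and DESeq2 42 higher and 536 lower. At an unadjusted p under 0.05 edgeR gave 763 higher and 1630 lower, 2393 in all, where 779 would be expected by chance. In simulated counts, drawn independently for each gene, 17.3% of DESeq2's calls and 3.95% of edgeR's were of unchanged genes. The groups did not overlap for 95 genes higher and 375 lower in Cdk7_KO, 3.02% of those tested, where chance gives 0.79%. Both chance values are averages, and genes that vary together can lie far from them without a genotype effect. In edgeR another division of the libraries into 5 and 5 called 738 genes. With the level of Xist as covariate edgeR called 38 genes higher and 619 lower, and with sex as a factor 46 and 686, of which 30 and 391 were also called by DESeq2. Within male or female libraries alone edgeR called 0 in both directions, while DESeq2 called 27 higher and 587 lower in males and 155 and 776 in females. Without Cdk7_KO replicate 1, edgeR called Nrp2 higher and Notch1, Abca1, Cdk7 and Il6st lower. DESeq2's lower count was 199 without Ctrl replicate 1, 262 without 3 and 341 without 5, and 329, 327 and 250 without Cdk7_KO replicate 2, 4 and 5. Its higher count was 18, 21 and 66 without Ctrl replicate 1, 5 and 6, and 66, 18, 74, 12 and 18 without Cdk7_KO replicate 1, 2, 3, 4 and 5. With the other-cell index as covariate DESeq2 called 1 gene higher, Gm13841, and 2 lower, Gm49980 and Cdk7.

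Summed marker levels of 10 of 12 other cell types were lower in Cdk7_KO, and none passed the correction over 17 measures. The exceptions were intermediate progenitors (262.7 and 265.8 CPM in Ctrl and Cdk7_KO) and hippocampal neurons (2024 and 2094 CPM). The latter are glutamatergic neurons of the dorsal forebrain, which NexCre may mark. Astrocyte markers summed to 2117 ± 641.0 CPM in Ctrl and 1119 ± 491.8 CPM in Cdk7_KO (SD, n = 5, two-sided exact permutation p = 0.0238, adjusted 0.0675). Endothelial and pericyte markers summed to 643.5 ± 521.7 and 215.6 ± 98.4 CPM (SD, n = 5, exact permutation p = 0.0238, adjusted 0.0675). Mitochondrial mRNAs took 1.06 ± 0.14% of counts in Ctrl and 0.858 ± 0.044% in Cdk7_KO (SD, n = 5, exact permutation p = 0.0159, adjusted 0.0675). The number of genes detected was 21140 ± 350.0 and 20290 ± 733.6 (SD, n = 5, exact permutation p = 0.0476, adjusted 0.101). The other-cell index, built after the data were examined, lay between 0.29 and 1.18 in Ctrl and between -1.88 (replicate 4) and 0.08 in Cdk7_KO. The first principal component of the 500 most variable genes held 45.5% of the variance (exact permutation p = 0.11 between genotypes).

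Longer genes were lower relative to shorter ones in the Cdk7_KO libraries. Across 15573 genes, which are not independent replicates, the rank correlation of a library's deviation with genomic gene length was 0.036 ± 0.065 in Ctrl and -0.050 ± 0.025 in Cdk7_KO (SD, n = 5, two-sided exact permutation p = 0.032). The difference of -0.087 did not pass with exon length (-0.073, exact permutation p = 0.19) or with genes of at least 5 CPM (-0.084, exact permutation p = 0.15). It was -0.016 within the male and -0.14 within the female libraries, where 5 libraries cannot give a p under 0.1. Without Ctrl replicate 5 or 6, or Cdk7_KO replicate 2 or 4, it was -0.078, -0.069, -0.082 and -0.079 (exact permutation p = 0.056, 0.056, 0.063 and 0.071).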

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

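The tests of sex by genotype, and those with the index, with sex or within the sexes, were chosen after the results were seen. A library stood far from the other 4 of its group in 15 of 292 groups of values, and chance alone gives about 15. Ctrl replicate 1 accounted for 7 of them, each a high value (ratio of gap to range in parentheses). They were the summed CPM of endothelial and pericyte genes (0.718, 1544 CPM against at most 648.5), Nos2 (0.821), Scarf1 (0.771), Dnaic2 (0.732), Serpinb6b (0.746), Msrb3 (0.870) and Stra6 (0.862). Ctrl replicate 6 was low in the scores of radial glia genes (0.810) and proliferation genes (0.804) and high in Osbp2 (0.852). Serpina3n was high in Ctrl replicate 5 (0.853) and low in Cdk7_KO replicate 4 (0.792). Csf1r was high in Ctrl replicate 3 (0.716), Col3a1 high in Cdk7_KO replicate 3 (0.740) and Rab3a low in Cdk7_KO replicate 1 (0.884).

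The genotype difference of 16 lists differed between male and female libraries by camera on the interaction term, and with an estimated correlation the smallest adjusted p was 0.471. In edgeR 0 genes had an interaction that passed (smallest adjusted p 0.665), with 1143 at an unadjusted p under 0.05, and no other tool was run on it. The lists with the smallest p were interneurons (median 0.46 in males, -2.06 in females) and cytosolic ribosomal proteins (-0.03 and 0.18).

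Camera called ribosomal protein and nuclear oxidative phosphorylation genes higher by small amounts and mitochondrially encoded mRNAs lower. With the other-cell index as covariate, camera called 3 of the 3 lists in the same direction (medians 0.09, 0.08 and -0.33). It also called 3 of 3 with sex as a factor (0.07, 0.07 and -0.25). These fits do not settle whether less RNA of other cells or an additive difference between the male and female sets is a source. The calls used the preset correlation, and the index did not overlap between genotypes (lowest 0.292 in Ctrl, highest 0.0787 in Cdk7_KO). With an estimated correlation none was called in these fits (adjusted p = 0.805 for each with the index) or in the female libraries (adjusted p = 0.468, 0.468 and 0.454). The pattern may rest on the female libraries, as 0 of the 3 lists were called within the male and 3 within the female libraries, with 2 or 3 mice per group. A genotype effect that depends on sex and a difference between the sets of preparations both stay open, as does RNA quality, since the gene length trend was likewise nearer to 0 in males (-0.016) than in females (-0.14) and the 100 most abundant genes took 15.8% of counts in Ctrl and 16.6% in Cdk7_KO (exact permutation p = 0.0318, adjusted 0.0771).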

How the results depend on the processing

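The settings with sex as a factor, the other-cell index, 2 surrogate variables or 1 sex, those of DESeq2 other than its own main test, and the leave-outs of the length trend, were chosen after the results were seen. The edgeR counts of 0 higher and 0 lower became 42 and 536 with DESeq2, 38 and 619 with the level of Xist, and 46 and 686 with sex. With 2 surrogate variables they were 5 and 1, the 5 being Kdm5d, Eif2s3y, Uty, Ddx3y and Ftl2-ps, of which the first 4 are Y-linked, and the 1 Cdk7. Without a filter 1 gene, Cdk7, was lower. Leaving out 1 library gave 0 to 1 higher and 0 to 4 lower, and the other edgeR and voom settings except the block kept both at 0. Replicate numbers 1, 3, 4 and 5 occur in both groups, and the labels name no shared animal. Deviations from the group means correlated at -0.104, 0.314, 0.143 and 0.173 between same-numbered libraries, so not every pair correlated, and 3 of 4 Ctrl libraries correlated best with their own number, a hint from the data, not the design. These 4 pairs are each of 1 sex, and all 12 Ctrl and Cdk7_KO pairs of the same sex correlated at 0.16 on average, against -0.15 for the 13 of different sex. With the replicate block over these 8 libraries edgeR called 0 higher and 5 lower (Abca1, Clu, Selenop, Atf3 and Hbb-bs), against 0 for the same libraries unpaired, and DESeq2 called 82 and 869, against 38 and 507 unpaired. The log2 fold change of Cdk7 was negative in all 27 alternatives (-1.76 to -1.09) and passed in 6, DESeq2 (-1.54), no filter (-1.54), the level of Xist (-1.44), sex (-1.43), 2 surrogate variables (-1.63) and without Cdk7_KO replicate 1, while leaving out 1 library gave -1.68 to -1.44. Of 83 other named genes 15 changed sign in at least 1 edgeR setting, 30 times in 2324 gene settings, and none of these values passed. With 1 surrogate variable these were Aqp4 (0.022), Gfap (0.16), Csf1r (0.051), Tbr1 (-0.035) and Ccn2 (0.21). With 2 surrogate variables they were Gfap (0.071), Csf1r (0.18), C1qa (0.083), Maf (0.23) and Gad2 (0.086). With the index they were Aqp4 (0.099), Gfap (0.24), Csf1r (0.28), C1qa (0.21), Maf (0.25), B2m (0.0072), H2-K1 (0.053), Tbr1 (-0.0031) and Ccn2 (0.16). With sex and the index they were Csf1r (0.12), C1qa (0.33), Cnp (0.22), Cspg4 (0.24), Maf (0.82), Gad2 (1.73), Enpp2 (0.024), H2-K1 (0.061), Rxrb (-0.0066) and Cdk9 (-0.0038), and in males Gad2 (0.47). Camera's 7 higher and 17 lower lists became 0 and 0 with an estimated correlation and with fry, 3 and 2 with the index, and 3 and 5 with sex and the index, and 6 to 7 and 14 to 20 without 1 library. They were 7 and 21 with sex as a factor, 5 and 16 in males and 6 and 16 in females. DESeq2's 42 and 536 genes became 132 and 1317 with sex and 1 and 2 with the index. Its higher count was 27 in males and 155 in females, and leaving out 1 library gave 12 to 74 higher and 199 to 770 lower. The length trend was -0.073 with exon length, -0.084 at 5 CPM or more, -0.016 in males, -0.14 in females and -0.11 to -0.069 without 1 library. TMM scaling left 0 library measures passing. Library totals in place of TMM factors shifted log2 fold changes over all genes by a median of -0.053. Camera then called 6 lists higher and 16 lower. Fewer libraries were fitted in each leave-out and within each sex, and for the other changes the cause was not tested. Depth limits the weakly expressed genes, such as Serpinb6b at 1.83 CPM in Ctrl.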

Other observations

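The tests of all drawn splits for lists and DESeq2 genes, of depth and of the neighbourhood of Cdk7 were written before their results were seen, and the other tests in this part after. Further genes called higher by DESeq2, picked after their values were seen, included the abundant noncoding transcript Gm42418, at 3568 ± 943.6 CPM in Ctrl and 5224 ± 1101 CPM in Cdk7_KO (SD, n = 5, log2 fold change 0.61, DESeq2 adjusted p = 0.0259, edgeR adjusted p = 0.183). Lars2, the mitochondrial leucyl-tRNA synthetase gene, had a log2 fold change of 0.53, Ppp1r1b, which encodes DARPP-32, one of 0.60, and Cirbp, a cold-inducible RNA-binding protein gene, one of 0.33. With sex as a factor, Gm42418 (0.70), Lars2 (0.585) and Mir6236 (0.65) were among edgeR's 46 higher calls, as were Gm15564 (0.90), Gm23935 (0.86) and Gm24270 (0.76). Whether these genes rose through a shared source of reads was not tested.

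Genes next to Cdk7 on chromosome 13 were looked at for carry-over of the region around the targeted allele. Of 111 tested genes within 10 Mb, DESeq2 called 2, Fam169a and Ccnb1, which is 1.80% against 3.67% of the other genes (one-sided Fisher's exact p = 0.918), and this argues against carry-over as a source of many calls.

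Marker genes of 10 other cell types fell in Cdk7_KO. The median of the 115 measured members was -0.942 after thinning to 23497621 counts and -0.936 before. Thinning keeps each gene's expected share of a library, so it could not decide on depth. Mean total counts were 26960000 in Ctrl and 25440000 in Cdk7_KO (exact permutation p = 0.373, adjusted 0.453). The median was -0.768 in the male and -1.39 in the female libraries, so the fall was seen in both sets. The 10 lists were picked from these same libraries, which favours negative values in both. Fewer cells of other types in the Cdk7_KO sorts is a candidate explanation, as the scores of the 10 lists correlated within groups at 0.36 on average over 45 pairs, with 7 pairs below 0. This average may rest much on Cdk7_KO replicate 4, whose astrocyte score was 3.28 against 4.57 in the next lowest library. It was not recomputed without that library. The most abundant members were Reln (1932 CPM in Ctrl, 1201 in Cdk7_KO), Ptprz1 (918.6 and 577.6) and Sparcl1 (591.3 and 404.9), the sort for the reporter would be meant to remove such cells, and 9 of the 129 listed members are in more than 1 list. Interneuron genes had opposite signs in males and females (adjusted p of that difference 0.471 in camera with an estimated correlation), and a genotype effect on these cells in the tissue was not tested and stays open.

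Genes called lower by DESeq2 varied with the same libraries. Of 527 lower calls outside the lists of the index, 97.2% had a positive correlation with it within groups, against 48.8% of all tested genes and 56.3% of uncalled genes of the same level. These shares may rest much on Cdk7_KO replicate 4, whose index was -1.88 against -0.74 in the next lowest library. They were not recomputed without it, and DESeq2 then called 327 genes lower. RNA of other cells may thus account for much of the lower side, and with the index as covariate DESeq2 called 1 gene higher and 2 lower, where Cdk7 kept its value (-1.62, SE 0.34). The index itself differs between the groups (0.62 ± 0.36 in Ctrl, -0.62 ± 0.79 in Cdk7_KO, SD, n = 5, exact permutation p = 0.00794), so the covariate also takes up genotype. After thinning, 525 genes were called lower, but thinning keeps each gene's expected share and so cannot decide on depth. A response of neurons that runs parallel to the index stays open.

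Of the 126 divisions of the libraries into 5 and 5, 100 were drawn, the real one included. For camera's lists, 2 of 100 gave as many as the real 24 (highest other 24, median 13). For DESeq2 on the genes edgeR tested, 4 of 100 gave as many as the real 559 (highest other 1683). Both shares are under 0.05 if libraries are exchanged across the male and female sets. As not all divisions were drawn and no correction was made over these counts, chance is not excluded. Among the 75 drawn splits with as many males and females per group as the real one, 2 gave as many lists (highest other 24) and 1, the real one, as many DESeq2 genes (highest other 390). For edgeR the real count of 0 is reached by any split (100 of 100, highest other 738), so that the splits say nothing about chance. A split that calls several times the real count points to another structure of the samples. The highest put Ctrl replicates 1, 3 and 4 with Cdk7_KO replicates 2 and 3. It lies near the division by sex, but that itself gave 86 DESeq2 genes, 22 edgeR genes and 15 lists, so sex alone does not account for it. Its sides, compared afterwards, did not overlap in the immediate early gene score (5.408 to 6.195 against 4.45 to 5.084). Nor did they in the score of injury-associated genes (5.265 to 5.596 against 4.67 to 4.999). What sets these libraries apart was not tested.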
